A study of Mus musculus with 16 samples.

How the data were processed

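RNA from whole uteri of ovariectomised mice was measured on 16 one-colour Cy3 Agilent 60-mer mouse arrays, 1 array per sample, from 200 ng of labelled total RNA per the labels' protocols. The 4 groups of 4 arrays were wild-type (WT) mice given vehicle (0 ug/kg, called PLB), WT mice given 8 ug/kg of 17beta-estradiol (E2), and mice of the genotype named Arg260 given the same 2 treatments, all sampled 6 h after injection. Groups and replicate numbers were taken from the sample labels. The 16 arrays lay on 2 slides of 8, each scanned separately, and each slide held 2 arrays of every group (replicates 1 and 2 on slide 1, replicates 3 and 4 on slide 2).

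The deposited scanner files hold spot intensities that the authors extracted with Agilent Feature Extraction 10.10.1.1, per the file headers and the submitters' processing notes. Per the file headers, the processed signal of a spot was background-subtracted and corrected for spatial trends within its array, and it was not normalised between arrays. The deposited series table holds log2 values of 37585 probes, and the submitters' processing notes name limma; the background correction and the filter behind the table are not given in the sources used here. Its 16 columns share 1 distribution (median 8.69 in each, range 4.40 to 19.1) and their ranks follow the spots' mean signal (Spearman 0.998 to 0.999 per array). The table is therefore on a log2 scale with quantile-normalised arrays; no centring of genes or reversed sign was found in it, and it was used as an alternative only. It lists 228 probes as missing, all of them on WT PLB replicate 2.

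Each array held 62976 spots, 59305 of them non-control spots of 55681 probes. Between 36505 and 41890 non-control spots per array (61.6% to 70.6%) were well above background by the deposited flags, and 0 were saturated. The number of arrays limits the precision: the median 95% interval of an E2 effect within 1 genotype extended 0.296 log2 units to either side, and that of the difference between genotypes 0.418.

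Values were log2 of the processed signal minus the log2 of each array's 75th percentile over non-control spots (percentiles of 922 to 1296 intensity units). Spots marked as non-uniform or population outliers were left out, and spots of 1 probe were averaged. A total of 38680 probes were well above background on at least 4 of the 16 arrays and entered the analysis. Probe names were updated through a table of the GRCm38.p6 annotation, used for names only: 27235 probes matched by accession, 3581 by symbol and 565 by synonym, and 24300 kept the name in the file, which can be old. The 1 probe with the highest mean over all arrays stood for each gene, which gave 25860 genes, 137 of them with a missing value on some array. Probe positions are those of the files, on mouse build mm9.

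Group means were fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom, 1 variance prior for all genes worth 1.97 degrees of freedom). The 5 tests were E2 against PLB in WT, E2 against PLB in Arg260, the difference of these 2 responses (the interaction), and Arg260 against WT in PLB and in E2. Tests were two-sided and adjusted over all genes tested by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Standard errors (SE) printed with log2 changes come from this fit, with n = 4 arrays per group. The size of the Arg260 response relative to WT was the total least squares slope through the origin over genes called for the E2 effect averaged over both genotypes, with an exact permutation of genotype labels within each treatment (4900 assignments) and a 95% interval from a jackknife over arrays. A fold for a probe that was not well above background on any array of a group is a bound: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

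The 35 gene lists (20 pathways and 15 sets of cell type markers), the tests, their thresholds and the alternatives were chosen before the data were examined, unless stated otherwise. Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison; fry, and camera with an estimated correlation, were alternatives. Members called are also counted when adjusted over the list alone.

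The genes named in the text follow a fixed rule. Esr1 and Pgr come first. For the E2 comparisons they are the 12 called genes with the largest rise and the 10 with the largest fall in WT, and those of the same ranks in Arg260, among probes well above background on all 4 arrays of the higher group and with an official symbol (no RIKEN, Gm, LOC, accession or probe names), with bounds where only a bound was measured. For the other comparisons they are all called genes if 20 or fewer, otherwise the 10 highest and 10 lowest, or, where none was called, the 5 genes with the smallest unadjusted p. For each list they are up to 4 called members with the largest absolute change and called members against the majority, or, where none was called, up to 2 with the smallest p. Genes named outside the rule are said to be so.

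The fit was tested on simulated data for 25723 genes with the arrays' own means and spread, in 5 draws with 200 changed genes each. For E2 in WT it called 41.5%, 72.5% and 91.2% of genes changed 1.5-, 2- and 4-fold; for E2 in Arg260 45.1%, 71.9% and 90.3%; for Arg260 against WT in E2 46.9%, 76.4% and 93.6%; and for the interaction 21.2%, 57.6% and 82.7%. Of unchanged genes, 0.0227% to 0.0282% were called. The simulated errors were independent between genes and few genes were changed, whereas the real E2 comparisons called 63.5% and 64.3% of genes. These rates therefore need not hold for the real data. Simulated slopes of 0.5 and 1 were recovered as 0.506 and 1.00 over the same genes.

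Each list's mean log2 signal per array was also put to an exact permutation of the array labels (70 assignments within 1 genotype or treatment, 4900 over both), adjusted over the 35 lists by Benjamini-Hochberg. The smallest p that 70 assignments can give is 0.0286. Within 1 genotype or treatment a list can therefore pass the adjustment only if many other lists reach that p too. The text names only some of the lists that passed within 1 genotype. Most alternatives changed 1 choice at a time, while normexp with quantile normalisation changed 2 and the deposited series table several. The alternatives were quantile normalisation; normexp background correction (offset 50) with the percentile or with quantile normalisation; the deposited series table; no filter on dim probes, or a filter asking for all 16 arrays; outlier spots kept; the mean of all probes of a gene; slide or replicate number as a block; only the groups compared in the fit; array weights; a trended and robust variance prior; each array left out in turn; and each slide alone. Leaving out the spots that the series table lists as missing, leaving out WT PLB replicate 2 and Arg260 PLB replicate 3 together, and the lists with each array left out or within each slide were added after seeing the data. Files were read with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6) and plots drawn with matplotlib 3.10.9. A few of the named genes are not reported here.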

Results

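Gene expression was measured in uteri of mice ovariectomised at 4 weeks of age, 2 to 3 weeks before treatment, so that the ovaries no longer supplied estrogen. The mice received 8 ug/kg of 17beta-estradiol (E2), or castor oil without it (PLB), under the skin, and uteri were taken 6 h later. They were wild type (WT) or carried a form of estrogen receptor alpha, the hormone's main receptor in the uterus and the product of Esr1, named for its arginine Arg260. The labels do not state how that arginine was changed. Each of the 4 groups (WT PLB, WT E2, Arg260 PLB and Arg260 E2) had 4 samples with 1 array each, and 36505 to 41890 spots per array were well above background. Replicates of a group correlated at 0.980 to 0.993 across genes, which are not independent replicates. The first principal component held 71.8% of the variance and parted all E2 from all PLB arrays, and on the second (5.12%) WT PLB replicate 2 and Arg260 PLB replicate 3 stood apart from the rest. Each sample has its own number in the labels, which do not say that the samples of a group came from separate animals. The p-values therefore measure only the spread between these samples, which need not be that between animals. Mean signals of adipocyte markers ranged from -3.54 to -0.44 within WT E2 and from 0.22 to 1.46 within Arg260 PLB. This argues against repeats of the same RNA in these groups.

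The first comparison asks what E2 did in the WT uterus. Esr1 itself did not pass the test (log2 change -0.04, SE 0.09, adjusted p = 0.760 in limma), while Pgr, the progesterone receptor gene and a classical estrogen target, rose 4.36-fold (log2 2.12, SE 0.20, adjusted p = 2.62e-07). The largest rise with a measured baseline was that of Gdf15, a stress-induced cytokine of the TGF-beta family, at 561-fold (log2 9.13, SE 0.29, adjusted p = 1.68e-11). The mitochondrial folate enzyme gene Mthfd2 rose 133-fold and the water channel gene Aqp8 91.2-fold. A total of 16434 of 25860 genes (63.5%) were called, 8245 higher and 8189 lower, and 7352 of the calls were at least 2-fold (3456 higher, 3896 lower).

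Among the other largest rises in WT, Mthfd2 rose by 7.06 (SE 0.22) on the log2 scale, the cardiac and slow-muscle myosin gene Myh7 by 7.25 (SE 0.27) and the muscle kinase gene Mylk2 by 6.77 (SE 0.16). Aqp8 rose by 6.51 (SE 0.25), the secreted protein gene Scube1 by 6.73 (SE 0.43), the glutathione-degrading enzyme gene Chac1 by 6.38 (SE 0.44) and Sprr2f, a small proline-rich epithelial protein gene, by 6.29 (SE 0.54). Trim15, the hormone gene Fgf21, the keratin gene Krt87 and the arginine deiminase gene Padi3 were not well above background on any WT PLB array, so that only bounds were measured: at least 174-fold, 58.2-fold, 94.3-fold and 69.7-fold higher. Among the largest falls, Pik3ip1, an inhibitor of phosphoinositide kinase signalling, fell by 5.09 (SE 0.23), the T-box gene Tbx6 by 5.07 (SE 0.27) and Ndp, which encodes a secreted ligand of Wnt receptors, by 4.84 (SE 0.15). The transcription factor gene Msc fell by 5.73 (SE 0.48; well above background on 1 WT E2 array) and the lipid droplet gene Cidec fell by 4.90 (SE 1.05). Ptgdr, a prostaglandin receptor gene, the lactate receptor gene Hcar1, Mc2r and Speer4cos were not well above background on any WT E2 array and were at least 42.0-fold, 13.8-fold, 12.4-fold and 16.3-fold lower. On mouse build mm9 the probes lie at chromosome 10, 5343056 to 5343115 (Esr1), chromosome 9, 8968492 to 8968551 (Pgr), chromosome 8, 73153293 to 73153352 (Gdf15), chromosome 7, 130611453 to 130611512 (Aqp8), chromosome 3, 92170259 to 92170318 (Sprr2f), and chromosome X, 16462804 to 16462863 (Ndp). The files do not say whether these stretches are coding. With slide as a block 16424 genes were called, within slide 1 alone 13891 and within slide 2 alone 11390. Of 56 named genes with more than 1 probe, probes of 4 (Esr1, Vcam1, Lifr and Wnt16) went opposite ways in a genotype. The 4 probes of Esr1 ranged from -0.53 to 0.25 in WT. For 7 of the 56 the probes lay at least 1 log2 unit apart in WT, among them Tbx6 (-5.07 to -2.22).

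**Figure D1:**
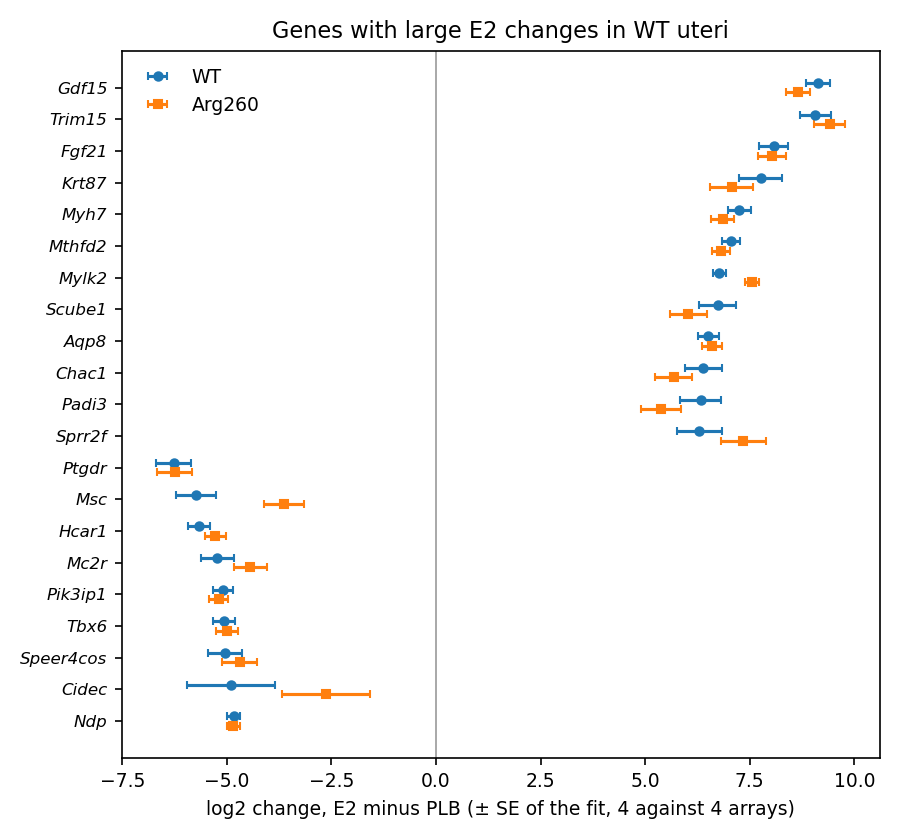
Log2 change 6 h after E2 (horizontal axis) of the 12 genes that rose most and 9 of the 10 that fell most in WT, for WT (circles) and Arg260 (squares), with the SE of the fit, n = 4 arrays per group. Points are differences of measured means, which are not bounds for the genes given as bounds in the text; Gdf15 lies at 9.13 in WT and 8.65 in Arg260.

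The same question was put to the Arg260 uterus. Pgr rose 5.18-fold (log2 2.37, SE 0.20, adjusted p = 8.01e-08), and the probe that stood for Esr1 fell by 0.35 (SE 0.09, adjusted p = 0.00475). Gdf15 rose 401-fold (log2 8.65, adjusted p = 2.25e-11), Sprr2f by 7.34, Mylk2 by 7.55, Mthfd2 by 6.82 and Aqp8 96.9-fold, and Trim15 and Fgf21 were at least 228-fold and 56.9-fold higher. Pik3ip1 fell by 5.19, Ndp fell by 4.85 and Ptgdr at least 19.4-fold. A total of 16628 genes (64.3%) were called, 8681 higher and 7947 lower, and 7399 of these calls were at least 2-fold (3622 higher, 3777 lower).

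Other named genes moved as follows in Arg260. Krt87 rose by 7.07 and Padi3 by 5.37 (each well above background on 2 Arg260 PLB arrays), Myh7 by 6.85, Scube1 by 6.03 and Chac1 by 5.69. The kallikrein genes Klk1b5 and Klk1b26 rose by 6.53 and 6.50 (6.14 and 6.11 in WT) and the aggrecan-cleaving protease gene Adamts4 by 6.51 (6.09 in WT). Tbx6 fell by 4.99, Msc by 3.63, Mcf2 by 4.99 (4.47 in WT), Fn3k, a kinase gene of deglycation, by 4.64 (4.36 in WT) and Sox1ot by 5.01 (3.51 in WT). The other probe of Sox1ot changed by -3.20 in Arg260 and -3.04 in WT. Hcar1, Mc2r and Speer4cos were at least 10.3-fold, 6.79-fold and 11.9-fold lower. Cidec fell by 2.63 (adjusted p = 0.0399), a call that ended without Arg260 E2 replicate 1 (0.102) or 2 (0.125) or Arg260 PLB replicate 2 (0.0943), 3 (0.0591) or 4 (0.0767). The Cidec call also ended with the fold unchanged with no filter (0.0567) or a trended robust prior (0.0519), and within slide 1 (log2 -4.04, adjusted p = 0.0880) and slide 2 (-1.22, 0.162). The Esr1 call was lost with the mean of its 4 probes (log2 -0.13, adjusted p = 0.225) and within slide 2 (0.286), and its probes ranged from -0.35 to 0.40. With slide as a block 16623 genes were called, within slide 1 14482 and within slide 2 11233.

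Known estrogen targets of the uterus, grouped in lists fixed beforehand, moved in the direction of their names in both genotypes. Of 28 estrogen-induced genes tested, 21 rose and 4 fell in WT (median log2 2.42, camera adjusted p = 8.74e-05) and 20 rose and 4 fell in Arg260 (median 2.87, adjusted p = 1.58e-04), with adjusted p = 0.246 and 0.233 with an estimated correlation. No camera call, in any of the 5 comparisons, held with an estimated correlation. Ramp3, a co-receptor of adrenomedullin, rose by 5.34 in WT and 5.39 in Arg260 (40.5- and 41.9-fold), the mitotic checkpoint gene Mad2l1 by 5.06 and 5.65, and Greb1 by 4.50 and 4.30. Against the name, Fzd2 fell by 1.80 and 2.17, Sox4 by 1.70 and 1.09, Sfrp4 by 0.93 and 1.14, and Lifr by 0.53 and 0.69. The Lifr calls were lost with the mean of its probes (adjusted p = 0.399 and 0.249) and within slide 2 (log2 -0.56 and -0.57, adjusted p = 0.177 and 0.168), and in WT also within slide 1 (-0.50, 0.134) and without WT PLB replicate 1 (0.0541) or WT E2 replicate 3 (0.0769). Of 12 estrogen-repressed genes 8 fell in each genotype, and 1 rose in WT and 2 in Arg260 (median -0.85 and -0.71, camera adjusted p = 0.0311 and 0.0355, or adjusted p = 0.343 and 0.275 with an estimated correlation). Without Arg260 E2 replicate 4 the Arg260 value was 0.0521. Txnip, which restrains glucose uptake, fell by 2.24 and 2.42, Ccng2 by 2.62 and 2.74, Cited2 by 2.35 and 2.18 and Zbtb16 by 2.42 and 1.86, the last not called in Arg260 within slide 2 (log2 -1.53, adjusted p = 0.162). Ihh, the signal from epithelium to stroma, rose by 1.82 in WT (adjusted p = 0.0122), a call that ended within slide 1 (log2 1.59, adjusted p = 0.138) and slide 2 (2.06, 0.0794), where the fold stayed about as large and the SE grew with fewer arrays. Its value of 1.40 in Arg260 (adjusted p = 0.0445) lost its call without Arg260 PLB replicate 1 (0.114), 2 (0.0952) or 4 (0.0522), Arg260 E2 replicate 1 (0.0863), 2 (0.109) or 3 (0.0796), or WT E2 replicate 2 (0.0536) or 3 (0.0504). It was also lost with slide as a block (0.0505), quantile normalisation (0.0712), normexp and quantile normalisation (0.0552), the series table (0.0637) or no filter (0.0630), and within slide 1 (log2 2.24, adjusted p = 0.0525) and slide 2 (0.57, 0.596). The medians of the induced list within slides 1 and 2 were 2.69 and 2.05 in WT and 2.76 and 2.69 in Arg260, and those of the repressed list -0.87 and -0.91 in WT and -0.83 and -0.72 in Arg260. Here and for the lists that follow, counts adjusted over the list alone equal those over all genes unless both are given. Median, mean, camera and fry had 1 direction for every list that camera called in any comparison. The uncalled E2 lists where they differ are pointed out.

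Genes that make the machinery of protein synthesis rose together in both genotypes. Of 37 ribosome biogenesis genes 36 rose and 0 fell in either genotype (median 2.07 and 2.09, camera adjusted p = 2.66e-18 and 1.23e-17, or adjusted p = 0.246 and 0.233 with an estimated correlation). Examples are Rrp12 at 3.84 and 3.57, Bysl at 3.44 and 3.36 and the nucleolar helicase gene Ddx21 at 3.32 and 3.28. Of 20 aminoacyl-tRNA synthetase genes 19 rose and 0 fell (median 1.75 and 2.02, adjusted p = 3.78e-10 and 2.20e-10, or adjusted p = 0.168 and 0.156 with an estimated correlation), with Aars at 4.06 and 4.01 and Yars at 3.83 and 4.10. Protein folding genes of the endoplasmic reticulum rose in 21 of 27 cases in WT and 23 in Arg260, with 0 falls (median 0.81 and 0.91, adjusted p = 9.40e-06 and 9.53e-06, or adjusted p = 0.379 and 0.358 with an estimated correlation). Not all members of this list fold proteins. It held the stress-induced transcription factor gene Atf4 (2.66 and 2.54) and its target Trib3 (3.78 and 3.63). The chaperone genes Hyou1 (1.97 in both) and Manf (1.97 and 1.98) rose less. Within slides 1 and 2 the ribosome medians were 2.03 and 2.12 in WT and 2.23 and 1.96 in Arg260, the synthetase medians 1.81 and 1.77 in WT and 2.03 and 1.94 in Arg260, and the folding medians 0.79 and 0.92 in WT and 1.04 and 0.83 in Arg260. All 37, 20 and 27 genes were well above background on all 4 WT PLB arrays too.

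Early-response genes, which answer growth signals within minutes, were higher 6 h after E2. Of 23 tested, 21 rose and 2 fell in WT and 20 rose and 2 fell in Arg260 (median 1.61 and 2.12, camera adjusted p = 8.74e-05 and 7.03e-05, or adjusted p = 0.379 and 0.358 with an estimated correlation; medians within slides 1 and 2 1.96 and 1.61 in WT, 2.10 and 2.21 in Arg260). Fosl1 was at least 8.48-fold and 11.5-fold higher, Fos rose by 3.39 and 4.21 and Ier3 by 3.03 and 2.71, whereas Ccn2 fell by 1.22 and 1.43 and Klf6 by 0.48 and 0.49. Within slide 2 the Ccn2 calls ended in WT (log2 -0.98, adjusted p = 0.137) and Arg260 (-1.36, 0.0576) and that of Klf6 in Arg260 (-0.36, 0.112). Of 17 MAP kinase feedback genes 10 were higher and 6 lower in WT and 11 higher and 5 lower in Arg260 (6 lower adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.231 and 0.217). Spry4 rose by 3.34 and 3.55, Errfi1 by 3.07 and 3.40 and the phosphatase gene Dusp5 at least 4.74-fold and 5.42-fold, while Etv5 fell by 1.77 and 1.60, Spry1 by 0.90 and 0.81 and Il17rd by 0.92 and 0.89. Nuclear receptor and coregulator genes were split, with 7 of 23 higher and 12 lower in WT and 7 higher and 13 lower in Arg260 (adjusted p = 0.691 and 0.340). The thyroid hormone receptor gene Thra fell by 2.61 and 2.92, and Nrip1 (2.31 and 2.27), Rara (2.06 and 1.94) and the arginine methyltransferase gene Prmt1 (1.66 and 1.70) rose. In WT the median of that list was -0.33 while fry, which asks whether the members move on balance 1 way, gave the direction up.

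The p53 target list held Gdf15 and the cell cycle inhibitor gene Cdkn1a (4.01 and 3.94, with its 3 probes from 0.93 to 4.02 in WT and from 0.93 to 3.94 in Arg260) and rose in both genotypes. In WT 12 of 18 rose and 2 fell (median 0.97, camera adjusted p = 0.0212, or adjusted p = 0.343 with an estimated correlation; 0.0513 without WT PLB replicate 2), and in Arg260 13 rose and 2 fell (median 1.11, adjusted p = 0.00715, or adjusted p = 0.233 with an estimated correlation). Its medians within slides 1 and 2 were 1.03 and 0.80 in WT and 1.14 and 1.01 in Arg260. The sestrin genes went opposite ways: Sesn2 rose by 3.33 and 3.08, and Sesn1 fell by 3.47 in both. Cell cycle lists did not pass camera at 6 h. An exact permutation of the list's mean passed G1/S and DNA replication in Arg260 (0.19, adjusted p = 0.0455) and over both genotypes (adjusted p = 0.0406) but not in WT (adjusted p = 0.567). The Arg260 value stems from the smallest p of 70 assignments, and passes only because many other lists reached it too. Of 30 genes of G1/S and DNA replication 12 were higher and 2 lower in WT (median 0.24, adjusted p = 0.294) and 11 and 2 in Arg260 (0.21, 0.445; 8 higher and 2 lower adjusted over the list alone). Pcna rose by 1.46 and 1.53 and Slbp by 1.16 and 0.99, whereas the helicase gene Mcm7 fell by 1.12 and 0.88. Of 27 genes of G2/M and mitosis 4 were higher and 2 lower in WT (median 0.14, adjusted p = 0.691) and 4 and 4 in Arg260 (median -0.20, 0.734, with the direction up in fry; 3 and 2 adjusted over the list alone), with Tpx2 at 2.35 and 2.39, Birc5 at 2.33 and 1.85 and the checkpoint kinase gene Bub1b at -1.96 and -2.09. Both WT values rest on WT E2 replicate 3, whose list mean was 0.80 for G1/S and -0.24 for G2/M, beside -0.27 to -0.21 and -2.41 to -2.21 on the other 3 WT E2 arrays. Without WT E2 replicate 3 the WT median was 0.04 for G1/S and DNA replication (adjusted p = 0.887) and -0.43 for G2/M and mitosis (adjusted p = 0.161).

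Cholesterol synthesis genes rose in both genotypes, 18 of 23 with 1 fall each (19 with 1 fall in Arg260 adjusted over the list alone; median 1.71 and 2.01, camera adjusted p = 8.74e-05 and 1.05e-04, or adjusted p = 0.662 and 0.677 with an estimated correlation). Sqle rose by 3.42 in both, and Acat2 fell by 0.77 and 0.61 (not called in Arg260 within slide 2, log2 -0.42, adjusted p = 0.0797). The list's medians within slides 1 and 2 were 1.5 and 2.10 in WT and 2.26 and 1.87 in Arg260. The WT rise of Idi1 by 5.58 (SE 1.32) rested in part on WT PLB replicate 2, where its probe read -8.36 against -0.67 to -0.26 on the other 3 arrays. Without that spot the rise was 3.62 (SE 0.341), beside 3.85 in Arg260. With the spot kept, the probe was not called in Arg260 within slide 1 (log2 4.16, SE 2.38, adjusted p = 0.186). That slide holds the spot, and the fit uses 1 spread for all groups, so the low WT reading widened this SE. Glycolysis genes did not pass camera as a list (8 of 18 higher and 4 lower in each genotype, median 0.22 and 0.28, adjusted p = 0.435 and 0.417): the hexokinase gene Hk2 rose by 4.11 and 4.18 and Pgam1 by 1.19 and 1.14, and Pfkm fell by 2.02 and 2.18 and Pdk1 by 1.19 and 1.22.

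Growth factor and vascular genes split into rises and falls. Of 28 angiogenesis and vascular tone genes 13 were higher and 8 lower in WT and 13 and 6 in Arg260 (median 0.36 and 0.38, camera adjusted p = 0.469 and 0.276): the placental growth factor gene Pgf rose by 5.49 and 5.18 and Vegfa by 3.75 and 3.43, and Vegfc fell by 2.20 and 2.18, Vegfd by 2.65 and 2.63 and Angpt1 by 3.10 and 3.58. Of 28 Wnt pathway genes 8 were higher and 14 lower in each genotype (9 and 14 in Arg260 adjusted over the list alone; median -0.27 and -0.38, adjusted p = 0.294 and 0.177). Wnt4 rose by 3.55 and 3.31, Wnt7b by 3.43 and 3.31 and the pathway's feedback gene Axin2 by 1.56 in both, and Rspo3, a Wnt enhancer, changed by -3.88 and -3.90 and Fzd1 by 2.53 and 2.30. In the IGF and growth factor list 5 of 27 were higher and 14 lower in WT and 5 and 15 in Arg260 (median -0.37 and -0.55, adjusted p = 0.0624 and 0.0727). Igf1, a local mediator of estrogen-driven growth, rose by 2.90 and 2.92 and Hbegf by 1.93 and 1.69, while Irs2 fell by 4.07 and 3.81 and Fgf10 by 3.47 and 2.95. Of 34 extracellular matrix genes 9 were higher and 11 lower in WT and 12 and 10 in Arg260 (adjusted p = 0.848 and 0.999). The hyaluronan synthase gene Has1 rose by 5.99 and 6.49 and Fbln2 by 2.81 and 2.90, Mmp11 fell by 3.46 and 3.49, and the list's median of -0.13 in WT and -0.11 in Arg260 stood against the direction up in fry and, in Arg260, a mean of 0.14. Of 19 clock genes 7 were higher and 10 lower in WT and 9 and 10 in Arg260 (median -0.63 and -0.48, adjusted p = 0.645 and 0.476), with Per3 (-3.07 and -3.23), Dbp (-2.92 and -3.18) and Nr1d1 (-2.80 and -3.29) lower and Nfil3 (2.60 and 2.96), Cry1 (1.44 and 1.61) and Clock (1.28 and 1.15) higher.

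Immune signalling genes moved in opposite directions in WT, with chemokines and cytokines higher and interferon-stimulated genes lower. Of 29 chemokine and cytokine genes 16 rose and 4 fell in WT (median 1.55, camera adjusted p = 0.0332, or adjusted p = 0.501 with an estimated correlation; 0.0725 without WT PLB replicate 2). Its median was 1.63 within slide 1 and 1.26 within slide 2, where the adjusted p was 0.0764. In Arg260 14 were higher and 2 lower (median 0.92, adjusted p = 0.0524). Cxcl1 rose by 4.33 and 3.59, Ccl7 by 4.28 and 4.39, Il6 at least 8.98-fold and 12.7-fold and Cxcl5 at least 10.9-fold in WT and by 4.48 in Arg260, and Il33 fell by 1.78 and 1.39. Of 26 interferon-stimulated genes 19 fell and 1 rose in WT (20 and 1 adjusted over the list alone; median -1.07, camera adjusted p = 1.29e-04, or adjusted p = 0.589 with an estimated correlation; medians -0.95 and -1.12 within slides 1 and 2), and 13 were lower and 4 higher in Arg260 (median -0.28, adjusted p = 0.0972). Ifit2 fell by 2.87 and 2.29, Rsad2 by 2.55 and 1.63, Ifit3 by 2.24 and 1.47 and Gbp3 by 2.01 and 1.29. Against them Mx1 rose by 1.97 in Arg260 (adjusted p = 1.44e-04). Its WT value of 0.85 (SE 0.34, adjusted p = 0.0429) was no longer called without WT E2 replicate 1 (0.117) or 3 (0.133), WT PLB replicate 2 (0.117) or 4 (0.110), or Arg260 PLB replicate 2 (0.0511) or 3 (0.0502). The WT call of Mx1 was also lost with slide as a block (0.0520), array weights (0.0680), no filter (0.0611) or only the compared groups (0.0638), and within slide 1 (log2 0.83, adjusted p = 0.245) and slide 2 (0.87, 0.221).

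Markers of cell types that a dissected uterus holds were tested as lists too. Of 14 endometrial stroma markers 8 fell and 0 rose in WT (median -0.62, camera adjusted p = 0.0190, or adjusted p = 0.559 with an estimated correlation; medians -0.64 and -0.61 within slides 1 and 2), and in Arg260 8 were lower and 2 higher (median -0.71, adjusted p = 0.0893). Dpt fell by 1.65 and 1.38, Lum by 1.37 and 1.56 and Hoxa10 by 1.19 and 1.20. The adipocyte list fell in WT, 9 of 10 with 0 rises (median -3.64, adjusted p = 0.0212, or adjusted p = 0.710 with an estimated correlation), with a median of -4.60 within slide 1 and -2.46 within slide 2. The fat hormone gene Adipoq fell by 4.30 (SE 1.14) and Fabp4 by 4.24 (SE 0.97) in WT. In Arg260 3 were lower (2 adjusted over the list alone; median -1.75, adjusted p = 0.215). All 10 adipocyte markers were well above background on all 4 WT PLB arrays. None of the other marker lists passed camera in either genotype. Epithelium had 7 of 17 higher and 2 lower in WT (6 and 2 adjusted over the list alone; median 0.19, adjusted p = 0.394) and 9 and 3 in Arg260 (0.34, 0.276). Elf3 rose by 2.64 and 2.24, Krt7 by 2.25 and 2.42 and Cldn7 by 1.73 and 1.93. An exact permutation of the epithelium list's mean gave adjusted p = 0.0476 in WT (0.46) and 0.0455 in Arg260 (0.54), each from the smallest p it can give, and 7.94e-04 over both. Uterine gland markers had 2 of 11 higher and 3 lower in WT (median -0.49, mean 0.21, adjusted p = 0.962 with the direction down, up in fry) and 3 and 1 in Arg260 (3 and 0 adjusted over the list alone; median -0.13, mean 0.36, 0.734 with the direction up), and Sox9 rose by 4.30 and 4.09. For smooth muscle the counts were 4 of 15 higher and 3 lower in WT (3 and 3 adjusted over the list alone; median 0.03, adjusted p = 0.848 with the direction down) and 2 and 4 in Arg260 (median -0.02, 0.476). Synm fell by 1.43 and 1.72 and Smtn by 0.84 and 1.06. Endothelium had 4 of 15 higher and 4 lower in WT (median -0.07, mean 0.08, 0.945) and 5 and 1 in Arg260 (0.08, 0.476), where Eng rose by 2.18 and 2.50 and Cldn5 fell by 2.17 and 2.05. The exact permutation of its mean gave adjusted p = 0.0833 in WT, 0.0455 in Arg260 (0.24) and 0.00136 over both.

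Blood and immune cell marker lists did not pass camera. An exact permutation of the list's mean gave neutrophil (mean 0.87) and erythroid markers (0.94) an adjusted p = 0.0455 each in Arg260, and macrophage markers (-0.29) 0.0476 in WT. These stem from the smallest p of 70 assignments, and pass only because many other lists reached it too. Over both genotypes neutrophil and erythroid markers passed (adjusted p = 0.00136 and 0.0250). Of 14 macrophage markers 2 were higher and 2 lower in WT (median -0.22, camera adjusted p = 0.757) and 2 and 3 in Arg260 (1 and 3 adjusted over the list alone; -0.59, 0.476), with Cd14 at -1.24 (not called within slide 2, log2 -1.12, adjusted p = 0.0870) and -1.27 and Fcgr1 at 0.90 and 1.03. Neutrophil markers had 5 of 11 higher and 1 lower in both (median 0.53 and 1.01, 0.435 and 0.359): Lcn2, which epithelium also makes, rose by 3.91 and 4.22 and Ly6g by 1.38 and 1.60, and Mmp9 fell by 2.12 and 2.06. Eosinophil markers had 0 of 9 higher and 2 lower in both (1 lower in Arg260 adjusted over the list alone; median -0.29 and -0.52, 0.691 and 0.480). Mast cell markers had 1 of 9 higher in both and 2 and 5 lower (median -0.35 and -0.57, 0.691 and 0.476). Lymphocyte markers had 1 of 17 higher and 3 lower in WT (1 and 0 adjusted over the list alone; median -0.14, 0.706) and 1 and 0 in Arg260 (-0.13, 0.734), and erythroid markers 1 of 7 higher and 0 lower (median 0.64 and 0.50, 0.469 and 0.476). Tissue that could be taken along in dissection was covered too: ovary markers had 2 of 8 higher and 2 lower in WT (1 and 2 adjusted over the list alone; median -0.24, 0.795) and 1 and 2 in Arg260 (-0.13, 0.664), with Inha at -2.10 and -2.20. Oviduct and ciliated cell markers had 0 of 10 higher and 6 lower in both (median -0.92 and -0.78, 0.161 and 0.217), with Ccdc39 at -1.59 in both. The exact permutation of their list mean gave adjusted p = 0.0476 in WT (-0.98) and 0.0455 in Arg260 (-0.88), again from the smallest p, and 7.94e-04 over both. Mesothelium markers had 1 of 9 higher and 5 and 6 lower (median -0.51 in both, 0.435 and 0.319), with Aldh1a2 at 4.00 and 3.91 and Rspo1 at -1.46 and -1.54. On all 4 WT PLB arrays 13 of the 14 macrophage, 16 of the 17 lymphocyte, 10 of the 11 neutrophil and 4 of the 8 ovary markers were well above background, and 14 of the 28 estrogen-induced genes are also members of another list.

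**Figure D2:**
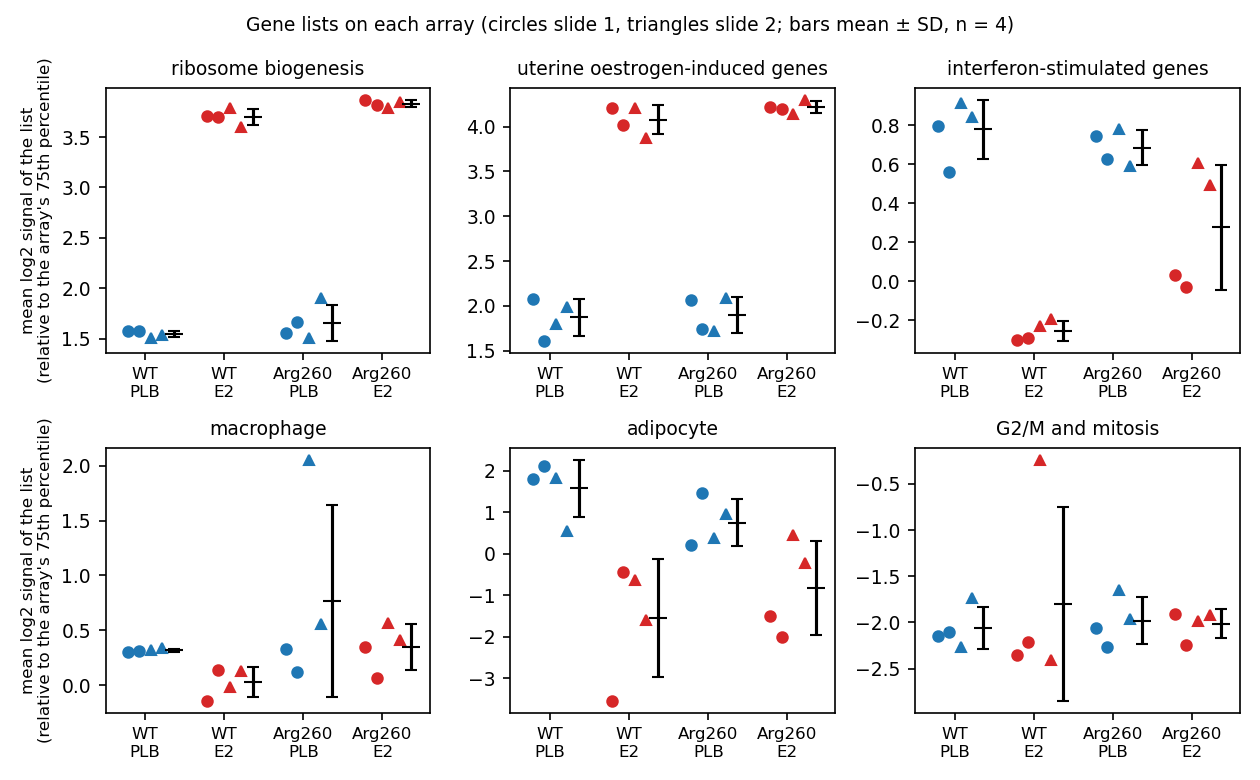
Mean log2 signal over the members of 6 gene lists on each of the 16 arrays, relative to the array's 75th percentile (circles slide 1, triangles slide 2), with the mean and SD of each group of 4. Macrophage markers stand at 2.06 on Arg260 PLB replicate 3 and G2/M genes at -0.24 on WT E2 replicate 3, apart from the other arrays of their groups.

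The next comparison asks whether the uterus responds differently to E2 when the receptor carries the Arg260 change. Across the transcriptome the 2 responses ran side by side: 14873 genes were called in the same direction in both genotypes (7699 higher and 7174 lower, against 2768 and 2517 for independent lists of those sizes). The slope of the Arg260 on the WT response was 0.997 (95% interval 0.935 to 1.06 over 18754 genes, exact permutation p = 0.950 over 4900 assignments, two-sided). The difference itself was called for 0 of 25860 genes in limma, with 961 (3.72%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.615. Pgr differed by 0.25 (95% interval -0.35 to 0.85) and Esr1 by -0.31 (-0.60 to -0.03), both with an adjusted p of 1. The responses correlated at a Pearson r of 0.951 and a Spearman rho of 0.937 across genes, which are not independent replicates. The 2 comparisons share no control arrays. Within slide 1 r was 0.904 and within slide 2 0.903.

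A difference missed by the test is not shown to be 0, and the intervals set its size. Among 7402 genes with an averaged change of at least 2-fold, the median absolute difference of the responses was 0.154 log2 units beside a median absolute response of 1.54, and for 5282 (71.4%) the 95% interval of the difference lay within 1 log2 unit of 0. For 6264 of them (84.6%) the interval put the Arg260 response above 0.5 times that of WT, and for 6316 (85.3%) the WT response above 0.5 times that of Arg260. The genes with the smallest p were Vcam1, the adhesion molecule gene (-0.07 in WT, 0.56 in Arg260, difference 0.62, 95% interval 0.40 to 0.85), and Il11, a cytokine gene needed for decidualisation (4.24 and 5.38, or 19.0- and 41.7-fold; difference 1.14, 0.72 to 1.56). They were followed by Gpsm2 (-0.87 and -1.60), Pfkfb1 (-1.85 and -0.88) and Inf2 (-0.35 and 0.21), with an adjusted p of 1. The adjusted p of Vcam1 and Il11 was 0.615. Of the WT-ranked genes, Msc had a difference of 2.10 (95% interval 0.66 to 3.54) and Mylk2 of 0.78 (0.29 to 1.26), both with an adjusted p of 1. In WT alone 1557 genes were called and in Arg260 alone 1751. 1455 and 1651 of these had the same sign in the other genotype, and 402 of the 3308 had an interaction p under 0.05 but 0 after adjustment. Both genotypes called 4 genes in opposite directions, named here after their values were seen: Inf2, Parp10 (-0.22 and 0.19), 4732423E21Rik (-0.32 and 0.28) and 1 probe without a gene name (0.44 and -0.28), each with an adjusted interaction p of 1.

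**Figure D3:**
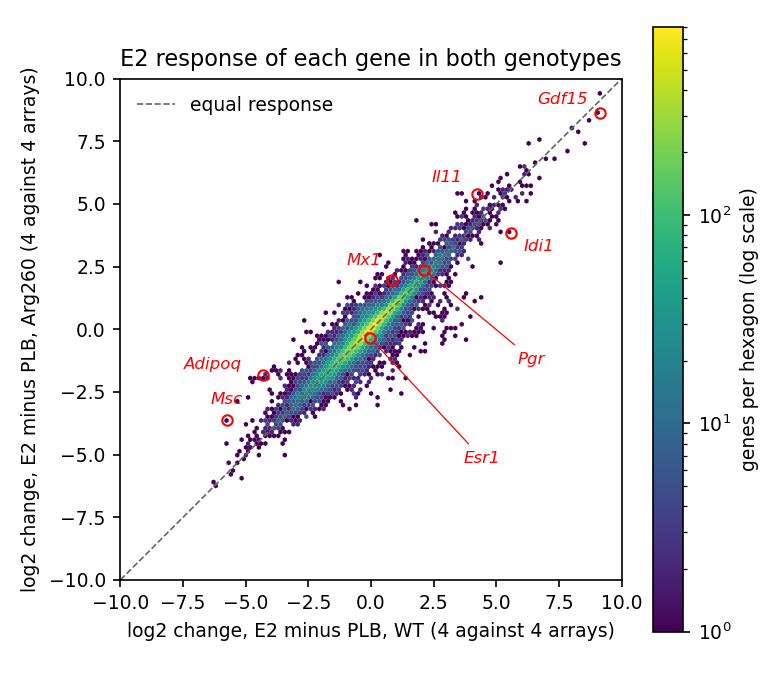
Log2 change 6 h after E2 of each gene in WT (horizontal axis) and Arg260 (vertical axis), 4 against 4 arrays in each, with colour for the number of genes per hexagon on a log scale and a dashed line of equal response. Circles mark Esr1, Pgr and 6 other genes of the text; genes spread along the line, with a Pearson r of 0.951.

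For gene lists, the E2 response of 6 differed between genotypes in camera, the interferon-stimulated genes most clearly. Their fall after E2 was smaller in Arg260: the median difference was 0.60 (camera adjusted p = 1.64e-19, or adjusted p = 0.294 with an estimated correlation), with 0 of 26 members called over all genes and 4 higher adjusted over the list alone: Rsad2, an antiviral enzyme gene (difference 0.92), Mx2 (0.88), Ifih1 (0.47) and Stat2 (0.47), the last 3 named after their values were seen. It was 0.24 within slide 1 (adjusted p = 0.00341) and 1.0 within slide 2 (4.79e-24). Over arrays, an exact permutation of the list's mean gave p = 0.00653, or 0.229 adjusted over the 35 lists. Adipocyte markers had a median difference of 1.95 (adjusted p = 6.66e-04; 1.47, 0.0644 within slide 1 and 1.99, 5.18e-06 within slide 2), lost without Arg260 E2 replicate 3 (0.0559). Adipoq had a difference of 2.48 (95% interval -0.98 to 5.94). The other 4 medians were small or turned with the slide. Nuclear receptors had -0.12 (0.00970; -0.19, 0.00605 within slide 1 and 0.02, 0.462 within slide 2), lost without Arg260 E2 replicate 1 (0.0680) or Arg260 PLB replicate 4 (0.0566). G2/M genes had -0.31 (0.00970; 0.21, 0.0644 and -0.95, 6.44e-04), lost without Arg260 PLB replicate 3 (0.198) or WT PLB replicate 3 (0.0579) and turned to 0.22 (0.0244) without WT E2 replicate 3. Endothelium had 0.15 (0.0174; 0.05, 0.911 and 0.30, 0.00782), lost without Arg260 PLB replicate 3 (0.199), Arg260 E2 replicate 3 (0.142) or WT PLB replicate 3 (0.0638). Smooth muscle had -0.15 (0.0178; -0.20, 0.0225 and -0.15, 0.263), lost without WT PLB replicate 1 (0.255), Arg260 PLB replicate 1 (0.0614) or 4 (0.517), Arg260 E2 replicate 2 (0.0566) or 4 (0.0662), or WT E2 replicate 2 (0.0661) or 3 (0.208). These 5 lists had 0 members called by either adjustment and adjusted p = 0.918 with an estimated correlation.

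Without E2, the comparison of Arg260 with WT asks whether the receptor change alters the resting uterus. Esr1 differed by 0.14 (SE 0.09) and Pgr by 0.01 (SE 0.20), both with an adjusted p of 1. In limma 0 of 25860 genes were called, with 638 (2.47%) at an unadjusted p under 0.05 and a smallest adjusted p of 1. The smallest p was that of Vcam1 (log2 -0.41, SE 0.07). The next belonged to 1700020G03Rik, which was not well above background on any WT PLB array, so that its difference was not measured, Cpne7 (-0.86, SE 0.22), Lypd1 (-0.65, SE 0.16) and an unnamed long non-coding RNA probe on chromosome 10 (0.92), all with an adjusted p of 1. Whether a receptor change is present cannot be read from these levels, since the array does not see the protein.

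Of the lists, 4 were called in PLB by camera, each with adjusted p = 0.837 with an estimated correlation and 0 members called by limma, also adjusted over the list alone. Ribosome biogenesis genes were higher by a median of 0.10 (adjusted p = 2.44e-08; 0.04, 0.104 within slide 1 and 0.18, 9.89e-06 within slide 2), lost without Arg260 PLB replicate 4 (0.0928). Adipocyte markers had a median of -0.95 (6.77e-04; -1.28, 3.07e-04 and -0.47, 0.0398). Endothelium had -0.12 (0.00363; -0.06, 0.595 and -0.20, 0.0181), lost without Arg260 PLB replicate 3 (0.380). Macrophage markers had 0.64 (2.14e-04; -0.01, 0.938 and 1.24, 7.87e-06), and without Arg260 PLB replicate 3, on which their mean stood at 2.06 against 0.12 to 0.55 on the other 3 arrays of the group, the median was 0.05 (0.396).

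The last comparison sets Arg260 against WT 6 h after E2. Esr1 differed by -0.17 (SE 0.09, adjusted p = 0.733) and Pgr by 0.26 (SE 0.20, adjusted p = 0.796). Limma called 0 of 25860 genes, with 1900 (7.35%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0724. The smallest p values were those of Gpsm2, which orients the mitotic spindle (log2 -0.76, SE 0.10, adjusted p = 0.0724), and Il11 (0.98, SE 0.14, adjusted p = 0.0768), followed by Fam170b (-0.80, adjusted p = 0.192), Lhx3 (-0.76, 0.282) and Tapbpl (0.37, 0.282). On each of the 4 Arg260 E2 arrays Il11 (1.34 to 1.63) lay above all 4 WT E2 arrays (0.30 to 0.69), and Gpsm2 (0.72 to 1.04) below them (1.47 to 1.80). Both genes were picked for the smallest p of 25860 on these same arrays, so this separation adds no support. Gpsm2 passed with an adjusted p of 0.00978 to 0.0483 and Il11 of 0.00508 to 0.0483 in some other settings, so that both stand at the edge of the test. Their probes lie at chromosome 3, 108482222 to 108482281, and chromosome 7, 4724847 to 4724906, on mm9.

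Interferon-stimulated genes were higher in Arg260 than in WT after E2, by a median of 0.52 over 26 members, all with a positive difference (camera adjusted p = 1.77e-18, or adjusted p = 0.344 with an estimated correlation). Over all genes 0 members were called by limma and 21 were higher adjusted over the list alone. Mx2 (0.76), Stat2 (0.40) and Ifih1 (0.38) had the smallest p, and are named after their values were seen. With slide as a block the adjusted p was 7.50e-21, within slide 1 the median was 0.21 (7.44e-04) and within slide 2 0.80 (2.58e-29), and leaving out any 1 array gave 2.89e-28 to 3.58e-09. Protein synthesis genes were slightly higher, ribosome biogenesis by 0.13 (2.28e-05; 0.12, 0.00124 within slide 1 and 0.11, 0.00423 within slide 2) and tRNA synthetases by 0.11 (0.00362; 0.08, 0.242 and 0.16, 0.00423). The other 5 lists called by camera changed with single arrays or slides. Cholesterol synthesis had a median of 0.22 (0.0264; 0.66, 1.07e-10 within slide 1 and -0.15, 0.0176 within slide 2), lost without WT E2 replicate 1 (0.874) or 4 (0.0935) or Arg260 E2 replicate 1 (0.229), 2 (0.0959) or 4 (0.0984). Nuclear receptors had -0.08 (0.0194; -0.16, 0.00649 and 0.00, 0.465), lost without Arg260 E2 replicate 1 (0.133) or 4 (0.0532) or WT E2 replicate 2 (0.0857) or 4 (0.0524). G2/M genes had -0.24 (0.0194; 0.19, 0.0711 and -0.77, 1.94e-04), lost without Arg260 E2 replicate 2 (0.113) and turned to 0.27 (1.60e-04) without WT E2 replicate 3. Clock genes had -0.10 (0.0194; -0.37, 7.44e-04 and 0.01, 0.962), lost without WT E2 replicate 1 (0.167) or 4 (0.0608) or Arg260 E2 replicate 1 (0.372). Smooth muscle had -0.11 (0.0467; 0.02, 0.368 and -0.19, 0.0332; 0.0504 with slide as a block), lost without WT PLB replicate 2 (0.0507), 3 (0.0538) or 4 (0.0525), WT E2 replicate 2 (0.158) or 3 (0.606), or Arg260 E2 replicate 2 (0.137), 3 (0.0713) or 4 (0.128). These 7 lists had 0 members called by either adjustment and adjusted p = 0.878 with an estimated correlation.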

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

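The tests of the interferon, macrophage and adipocyte patterns were chosen after those results were seen, except the test of a regional defect, and the regroupings of arrays were planned.

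Interferon-stimulated genes were higher in Arg260 than in WT 6 h after E2. Camera called their E2 response different between the genotypes (adjusted p = 1.64e-19). That call was lost with an estimated correlation (adjusted p = 0.294), with fry, and in an exact permutation adjusted over the lists (adjusted p = 0.229). The mean of the list per array lay between -0.03 and 0.61 on the 4 Arg260 E2 arrays and between -0.30 and -0.19 on the 4 WT E2 arrays. The difference of 0.53 had an exact permutation p = 0.0286, the smallest that 70 assignments can give. Adjusted over the 35 lists that p became 0.5. No list could pass this adjustment unless many others were also at the smallest p, so it does not decide. Each slide held 2 arrays of each group, so that a slide effect common to the groups cancels from the difference; slide 2 exceeded slide 1 by 0.0847 in WT E2 and by 0.552 in Arg260 E2, and a slide effect on the Arg260 E2 arrays alone stays open. More immune cells in the Arg260 E2 samples cannot be told apart from a change within the same cells. Macrophage markers were higher there by a median of 0.290 (SE over the markers 0.0956), over 0.5 times the median shift of the interferon list. Lymphocyte markers were higher by 0.118 (SE over the markers 0.0443), under 0.5 times that shift. These SE are over genes on the same 8 arrays and not over samples, so they do not decide about either cell type. Over arrays, an exact permutation of the list's mean gave p = 0.0857 for macrophage and p = 0.371 for lymphocyte markers. Genotype may account for the pattern and stays a hypothesis, found and tested on the same 8 arrays.

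Macrophage markers, called higher in Arg260 than in WT without E2 (camera adjusted p = 2.14e-04, or adjusted p = 0.837 with an estimated correlation), came from 1 array. Without Arg260 PLB replicate 3 the median difference fell from 0.636 to 0.0484, which argues against genotype. On that array the 14 markers lay a median of 2.03 log2 units above the other 3 arrays of the group, 8 of them by more than 1, with Adgre1 at 4.39, Aif1 at 4.09, Cx3cr1 at 2.97 and Csf1r at 0.75 but Mrc1 at -0.87 and Cd163 at -1.58. Cd163 was the dimmest of the 14 (-8.17 there, -6.59 on the other 3), so its difference is poorly measured. A defect in a region of the array is argued against: 34.4% of the probes at least 2 log2 units above the other arrays had another such probe within 5 spots, beside 36.5% of random probes. Other cells in that sample may be the source, while Mrc1, which was lower, leaves open which cells these would be.

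Adipocyte markers were lower after E2 and varied widely among arrays of a group, from -3.54 to -0.44 in mean log2 signal within WT E2. Their deviations from the group means went together over the 16 arrays (median pairwise correlation 0.782, where random lists stayed below 0.171 in 39 of 40), which is consistent with varying amounts of fat among the samples. The fall with E2 itself passed an exact permutation of treatment labels within genotypes (p = 0.00122), so that E2 may lower either the fat taken with the uterus or the genes in it. The difference of the fall between genotypes, 1.55 in the mean, had an exact permutation p = 0.133 and cannot be told apart from chance variation in fat with 4 arrays per group; camera had called it (adjusted p = 6.66e-04, or adjusted p = 0.918 with an estimated correlation).

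Other splits of the arrays argue against chance for the E2 genes alone. With genes complete on all arrays, the real split of the 8 arrays called 16354 genes in WT and 16548 in Arg260. The highest of the other splits called 0 and 1. Only 1 of 35 splits was as large in each, the smallest share that 35 splits can give. Each other split puts E2 and PLB arrays on the same side, so a true E2 effect widens its spread. For the number of lists that camera calls chance is not excluded in any comparison, though 16 of the 34 other splits in each E2 comparison kept 3 of the 4 arrays of a treatment together and so still carry E2. As many lists as the real 12 in WT came from 13 of 35 splits (highest other 17), as the 8 in Arg260 from 22 of 35 (15), as the 6 for the difference of the responses from 88 of 100 drawn splits (15), as the 4 in PLB from 30 of 35 (16) and as the 8 after E2 from 22 of 35 (13). In WT nearly all other splits with at least 12 lists, the highest among them, kept 3 arrays of a treatment together, so the WT count cannot decide about chance. In Arg260 splits with 2 arrays of each treatment on either side also reached 8 lists, up to 11. An exact permutation of each list's mean over both genotypes, which asks whether the list moved and not whether it moved more than other genes, passed 25 of 35 lists, 18 of them at the smallest p it can give (p = 0.000408, adjusted p = 7.94e-04). These 18 include ribosome biogenesis but also lists that camera did not call, such as glycolysis and the Wnt pathway, so it sets none of them apart. For genes that limma calls by genotype the count of 0 leaves nothing to test, since any split has as many: 100 of 100 for the difference of the responses and 35 of 35 in PLB and in E2 (highest other 2 in each). At an unadjusted p under 0.05, 63 of 100 splits gave as many as the 959 genes of the interaction (highest other 3283), 33 of 35 as many as the 636 in PLB (2318) and 7 of 35 as many as the 1893 after E2 (3746), so that chance is not excluded for these counts. Splits with over 3 times the real number, as in PLB and for the difference of the responses, may reflect a structure of the arrays or genes that vary together, which was not tested. The split of the E2 arrays by slide gave 1466.

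Other lists whose E2 response differed between genotypes in camera were nuclear receptors and coregulators (adjusted p = 0.00970), G2/M and mitosis (0.00970), smooth muscle (0.0178) and endothelium (0.0174), each lost with an estimated correlation (adjusted p = 0.918). Each call also ended without some single array (highest adjusted p 0.0680, 0.198, 0.517 and 0.199), and G2/M turned up without WT E2 replicate 3 (0.0244). Among the named genes, 1 array stood apart from the other 3 of its group in 53 of 916 sets of 4 (5.79%), and among the lists in 7 of 140 (5%), where chance gives about 1 in 20. The 53 were not spread evenly: 14 were on Arg260 PLB replicate 4 and 10 on Arg260 E2 replicate 1, and any other array held at most 5. Of the 53, 3 are not listed here. The number after each name is the gap to the nearest array as a share of the group's range. On Arg260 PLB replicate 4 these were Hcar1 (0.860), Adamts4 (0.833), Greb1 (0.835), Vegfa (0.874), Irs2 (0.83), Timp1 (0.837), Col6a1 (0.877), Col6a3 (0.981), Eln (0.955), Cldn7 (0.892), Ccr3 (0.840), Cma1 (0.858) and Rspo1 (0.899). Arg260 E2 replicate 1 held Chac1 (0.928), Vcam1 (0.877), Nrip1 (0.922), Yars (0.943), Trib3 (0.882), Pgf (0.839), Tek (0.958), Fzd1 (0.907), Ccl5 (0.934) and Hoxa10 (0.887). WT E2 replicate 3 held Pfkfb1 (0.887), Tpx2 (0.872), Cenpa (0.895) and Cxcl1 (0.848), and the lists of endoplasmic reticulum folding (0.875), G1/S (0.844) and G2/M (0.941). WT PLB replicate 2 held Idi1 (0.949), Cx3cl1 (0.852), Sox9 (0.919), Fcgr1 (0.835), Mrgprb2 (0.843) and the gland list (0.904). WT PLB replicate 4 held Birc5 (0.903), S100a8 (0.877), Ahsp (0.938) and Gpm6a (0.837), and WT PLB replicate 3 held Eno1 (0.857), Prss29 (0.949) and Dynlrb2 (0.925). For Arg260 PLB they were Fzd2 (0.835) and Nr1d1 (0.917) on replicate 1, Trim15 (0.885), Pdk1 (0.840) and the erythroid list (0.854) on replicate 2, and Esr1 (0.860), Cd14 (0.889) and the gland list (0.870) on replicate 3. The rest were Sqle (0.932) on Arg260 E2 replicate 3, Pfkfb1 (0.854) on Arg260 E2 replicate 4, Fzd2 (0.925) on WT E2 replicate 1, Spry1 (0.866) and Dll4 (0.852) on WT E2 replicate 4, and the cholesterol list (0.834) on WT PLB replicate 1.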

How the results depend on the processing

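The lists within slides or with arrays left out, the series table's missing spots left out, and 2 arrays left out together were settings chosen after seeing the data. The counts of E2 genes stayed within 1.5 times their reported values in every setting run, and the genotype difference of the response and Arg260 against WT in PLB kept 0 called genes by limma throughout. The balance of rises and falls turned with the scaling. In Arg260, 8681 higher and 7947 lower became 8205 and 8670 with quantile normalisation, 8042 and 8570 with normexp and quantile normalisation and 8236 and 8558 with the series table. In WT, 8245 and 8189 became 8005 and 8773 with quantile normalisation. Arg260 against WT in E2 went from 0 genes to 1 with quantile normalisation or array weights, 2 with normexp, the series table, the stricter filter, or a trended robust prior, 3 with normexp and quantile normalisation, and 0 to 2 with single arrays left out; these were Gpsm2, Il11, Fam170b and Lhx3, and the cause was not tested. The slope of the 2 responses stayed within its jackknife error in each setting. Their correlation of 0.951 became 0.971 with normexp, 0.969 with normexp and quantile normalisation, 0.970 with the series table, 0.905 without a filter, 0.974 with the stricter filter, and 0.904 and 0.903 within slides 1 and 2, where fewer arrays enter. Genes shared by both genotypes fell from 14873 to 9576 within slide 2, with fewer arrays too. With replicate number as a block, 16393 genes in WT and 16672 in Arg260 were called; the numbers do not pair the samples (3 of 24 same-number pairs correlated over 0.1, median 0.0284, and 5 of 16 arrays correlated best with their own number).

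Camera called 38 of 175 lists over the 5 comparisons, 0 with an estimated correlation and 58 within slide 2. With fry, which asks whether a list moved and not whether it moved more than other genes, all genotype calls were lost, the interferon list's among them. These were 6 in the difference of responses, 4 in PLB and 8 after E2. The E2 calls within a genotype were kept with fry, and 10 lists in WT and 16 in Arg260 were added. The following lists turned direction, as adjusted p, and the cause was not tested. With fry, uterine gland in WT turned up (0.0114). Within slide 1 it was G1/S (0.00575) and G2/M (0.0644) in the difference of responses, macrophage in PLB (0.938), and G1/S (2.62e-05), G2/M (0.0711) and mesothelium (0.0396) after E2. Within slide 2 it was protein folding (0.0477) and cholesterol (0.00597) in the difference of responses, and cholesterol (0.0176) and clock genes (0.962) after E2. Without WT PLB replicate 2 and Arg260 PLB replicate 3, macrophage turned in the difference of responses (0.0189). With single arrays left out, the difference of responses ranged over 0.0146 to 0.960 for ribosome biogenesis, 0.00144 to 0.679 for G1/S and 1.57e-05 to 0.198 for G2/M, and the difference after E2 over 1.67e-07 to 0.955 for G1/S and 1.05e-05 to 0.113 for G2/M. No named gene changed direction while called. Of 14947 gene values and 4375 list values, 19 and 210 changed sign with no call on either side and are not counted as turned. Probes under background limit the measured folds to bounds.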

Other observations

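The list of Atf4 target genes below was chosen after the named genes were seen, and its prediction was written before its own values were looked at; the remarks on WT PLB replicate 2 rest on tests chosen after the data were seen.

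Several genes of amino acid synthesis and transport, picked from the list of Atf4 targets below after its values were seen and not tested as a group of their own, rose 6 h after E2. The asparagine synthetase gene Asns rose by 4.04 in WT and 4.29 in Arg260, and the serine pathway genes Psat1 by 3.81 and 3.93, Phgdh by 2.81 and 3.02 and Psph by 2.73 and 2.82, with Shmt2, which passes serine carbon to folate, at 2.16 and 2.33. Among transporters, Slc7a5, which carries large neutral amino acids, rose by 3.98 and 3.96, Slc7a1, which carries cationic ones, by 3.75 and 3.49, and the cystine carrier gene Slc7a11 by 3.33 and 2.19. Aldh18a1 of proline synthesis rose by 2.72 in both, the tRNA exporter gene Xpot by 2.42 and 2.43 and the translation inhibitor gene Eif4ebp1 by 2.47 and 2.55. Other listed genes of this kind rose less in WT, Slc6a9 by 1.51 and Cth by 1.47, and Gpt2 (0.29, adjusted p = 0.179) was not called there. All these genes are targets of the transcription factor Atf4, as are Chac1, Mthfd2, Trib3, Fgf21 and Gdf15 among the named genes.

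The hypothesis was that the genes with the largest rise share a wider rise of Atf4 targets. In a list of 23 other Atf4 targets, none of them named before or held by the fixed lists, 21 rose and 0 fell in WT and 22 rose and 0 fell in Arg260, with medians of 2.16 and 2.19. In 39 of 40 of 10000 draws, random lists matched on mean level stayed below 0.611 in WT and 0.646 in Arg260, and none reached these medians. An exact permutation of the list's mean gave p = 0.0286 in each genotype, the smallest that 70 assignments can give, and 0.000408 over both, the smallest of 4900; the genotypes differed by 0.05 in the mean (exact p = 0.683). Random lists matched on level alone cannot tell Atf4 targets from other genes that rose with E2. The mean of the ribosome biogenesis list rose about as much, by 2.15 in WT and 2.17 in Arg260. The mean of the Atf4 targets rose by 2.18 and 2.23. Activation of Atf4 by 6 h may be part of the response in both genotypes, but this test does not set it apart. Its activity was not measured and other factors could raise the same genes. Pck2, another listed target, was at 0.29 in WT and 0.36 in Arg260 without a call.

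On WT PLB replicate 2, 71 genes lay at least 5 log2 units below the other 3 arrays of the group. Of 206 probes at least 2 log2 units below, 85.0% had another such probe within 5 spots, beside 23.0% of random probes. Of the 228 probes that the series table lists as missing on this array, 157 belong to tested genes. These lay a median of -5.30 log2 units from the other arrays, and Idi1 is among them. The main fit kept these spots unless they were flagged as outliers. Leaving them out gave 16507 E2 genes in WT, beside 16434 in the main fit. On Arg260 PLB replicate 3, 302 genes lay at least 2 log2 units above the other arrays of its group, where the other 15 arrays of the series had 40 to 165.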
